A study of Mus musculus with 10 samples.

How the data were processed

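Total RNA from the cortex of single mouse embryos at E10.5 was measured on whole-transcript Affymetrix GeneChip 1.0 ST arrays, with 5 arrays of wild-type C57BL/6 embryos and 5 of embryos heterozygous for the Mos2 allele of Magoh. Per the labels' protocols, the cortices were taken as a pair from each embryo, RNA was extracted with Trizol and 300 ng was labelled per array. The labels call the arrays of a genotype biological replicates, so p-values of single genes and of permutation tests measure the spread between embryos. The gene list test at a preset correlation and the test of genes near Magoh compare genes with other genes. Their p-values do not measure that spread. Litters and hybridisation days could not be tied to the arrays, so no batch was tested.

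The deposited values are log2 expression values, 1 column per array, which were made with Affymetrix Expression Console and RMA per the submitters' processing notes. RMA corrects background, normalises between arrays and summarises the probes of a probe set on the log2 scale, so a level common to all genes of an array is removed and fold changes tend to be compressed. Software versions and the annotation used by the authors are not given in the sources used here. The deposited annotation columns (other text: sequence accession, Entrez gene number and title) named the probe sets. A second deposited table holds 10 columns of per-sample values whose names could not be tied to the labels, and none of these was used. What the names stand for is not stated, and they could hold a grouping of the embryos that was not analysed here. Arrays have no sequencing depth, and their number limits the precision. No detection calls were used. As a guide to background, the 95th percentile of the negative-control probe sets averaged 8.57 over the 10 arrays, with medians between 5.34 and 5.82. The difference of a gene with a level below 8.57 in either genotype can include background, and its size is approximate. The median over all genes was 7.15 to 7.23 per array, so most genes lay below 8.57 and the limit is not particular to the genes named.

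Of 35557 probe sets, 6546 were controls. Entrez numbers were deposited for 24415 probe sets, of which 23322 matched the gene table of assembly GRCm38.p6, and 465 more were matched by accession. A further 1919 carried an identifier with no match and 3305 carried none, and these were left out of the comparison by gene. Where several probe sets named a gene (1929 genes), the probe set with the highest mean over all arrays was kept, which left 20405 genes. No filter was set on dim probe sets. The titles of some probe sets refer to another assembly, so no coordinates are given and the gene table served only for names, order and distance along a chromosome.

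Before the data were examined, the tests, the alternatives, 28 gene lists and the rule for named genes were fixed. Mutant minus wild type was fitted per gene with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 10 arrays, without covariates, and p-values were adjusted by Benjamini-Hochberg over the 20405 genes. Genes with an adjusted p under 0.05 were called. Gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 27 lists, and beside it with camera's estimated correlation and with fry. The list of transcripts of the mitochondrial genome matched 0 gene names and was left out. The array did measure 7 genes placed on that genome, of which 0 were called, so this sign of sample quality was not tested as a list. Members of each list were also adjusted over the list alone. Single values and list means were compared by an exact two-sided permutation test, whose smallest possible p was 0.00794. Genes with an unadjusted p under 0.01 within 20 Mb of Magoh were compared with all other placed genes by Fisher's exact test, two-sided.

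Named without regard to their values were Magoh, Magohb, Rbm8a, Eif4a3, Casc3 and Pafah1b1. To these were added the 12 largest rises and the 12 largest falls among called genes whose values in the 5 arrays of each genotype did not overlap, and up to 4 members of each list with the smallest p. Genes named outside this rule are said to be so. Lists covered the exon junction complex, nonsense-mediated decay and its known substrates, small brain size, Lis1 and dynein, the cell cycle, p53 targets, stress and metabolism, ribosomal proteins, progenitors and neurons. Other lists covered cells that a dissection could include and signs of sample quality, among them sex-linked, immediate early, small nucleolar RNA and histone genes.

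Alternatives were quantile normalization, centring on array medians, leaving out dim genes by mean at 2 limits, testing every probe set, an intensity trend with robust variance, array weights, the replicate number as a block, a sex covariate, other thresholds and windows, and leaving out each array in turn. An alternative that left out mutant arrays 1 and 5 together was chosen after seeing the data. The fit and the list test were tested on simulated data with the spread of the 20405 genes. At a log2 difference of 0.5, 82% of 100 changed genes were recovered, and at 1, 100%. Of 191 calls, 9 were false, and 0 unchanged lists were called. The simulated genes varied independently of each other. The 0 therefore does not show how often list calls arise among genes that vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with tables read by pandas 2.3.3.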

Results

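Expression was measured in the cortex of 10 mouse embryos at E10.5, an age at which the wall of the cortex is mostly dividing progenitors and the first neurons are being born. There were 5 wild-type embryos and 5 embryos heterozygous for a mutant allele of Magoh, which encodes a core protein of the exon junction complex, the set of proteins left on mRNA where exons were joined. The comparison asks which transcripts differ in mutant cortex. Values are log2 RMA levels, differences are mutant minus wild type, and spreads are SD over n = 5 arrays.

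Magoh itself (Entrez 17149, chromosome 4) was lower in every mutant array. Its level was 11.05 ± 0.09 in wild type and 10.21 ± 0.18 in mutants, a log2 difference of -0.84 (SE 0.08), or 0.559 of the wild-type level (limma, adjusted p = 8.5e-05). The 5 mutant arrays lay between 9.92 and 10.37 and the wild-type arrays between 10.90 and 11.14, so the labels and the level of the mutated gene go together. Its close paralog Magohb differed by 0.02 (SE 0.09, limma adjusted p = 0.975), at levels below 8.57, the mean 95th percentile of the negative controls, where background can hide a change. The partners Rbm8a, Eif4a3 and Casc3, the other core proteins of the complex, differed by 0.07, 0.03 and 0.11, with limma adjusted p of 0.817, 0.955 and 0.737. The sign of Magohb and Eif4a3 turned when single arrays were left out. With 1 array left out, Rbm8a lay between 0.05 (without mutant array 2) and 0.11 (without mutant array 1), and Casc3 between 0.06 (without mutant array 1) and 0.14. Of the 16 measured genes of the exon junction complex list, 0 rose, 1 fell (Magoh) and 15 did not pass, and adjusted over the list alone the count was the same 1. The median of that list was 0.03 and its mean -0.01, so the 2 differ in sign. Pafah1b1, which encodes Lis1, a dynein regulator whose loss gives a smooth brain, differed by -0.22 (SE 0.11, limma adjusted p = 0.547). Without mutant array 1 that difference was -0.12.

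Genes activated by p53 gave the largest rises in mutant cortex. The death receptor gene Eda2r rose 5.09-fold, from 5.87 ± 0.22 to 8.22 ± 0.37, and the cell cycle inhibitor Cdkn1a (p21) rose 3.10-fold, from 6.76 ± 0.10 to 8.39 ± 0.34. Ccng1 rose 2.87-fold, Phlda3, an inhibitor of Akt, 2.17-fold and the RNA-binding gene Zmat3 2.17-fold. The wild-type level of Eda2r lay close to the medians of the negative controls, 5.34 to 5.82, so its fold includes background. Cdkn1a lay below 8.57, the mean 95th percentile of the negative controls, in both genotypes, and Phlda3 and Zmat3 lay below it in wild type, so these folds are not exact either. In limma the adjusted p of these genes was 1.1e-06 for Eda2r, 5.5e-06 for Cdkn1a, 3.6e-06 for Ccng1, 3.8e-05 for Phlda3 and 8.5e-05 for Zmat3. Chosen after their values were seen, the proapoptotic gene Bax rose by 0.43 and the nuclease gene Aen by 0.56 on the log2 scale, both from wild-type levels below 8.57. Mdm2, the p53 ubiquitin ligase and itself a p53 target, was likewise chosen after its value was seen and differed by 0.08 (limma adjusted p = 0.844), with 0.02 without mutant array 2 and 0.14 without mutant array 1.

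Of 36 measured p53 targets, 13 rose, 0 fell and 23 did not pass. Adjusted over the list alone, 19 rose and 2 fell. The median log2 difference of the list was 0.20 (camera adjusted p = 5.1e-21), with adjusted p = 0.0129 with an estimated correlation and 0.000325 with fry. Its mean was higher in 5 of 5 mutant arrays than in any wild-type array, with a difference of 0.39 (exact two-sided permutation p = 0.00794, the smallest possible; adjusted over 27 lists 0.0429). Between 11 and 14 targets were called with any 1 array left out. Among members singled out after their values were seen, the call of Trp53inp1 (0.59) was lost without 9 of the 10 arrays, with limma adjusted p up to 0.144, and that of Pvt1 (0.54, with both levels below 8.57) without 5, up to 0.117. Red cell markers were higher in mutants by a median of 0.25 (adjusted p = 0.264 with an estimated correlation).

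**Figure D1:**
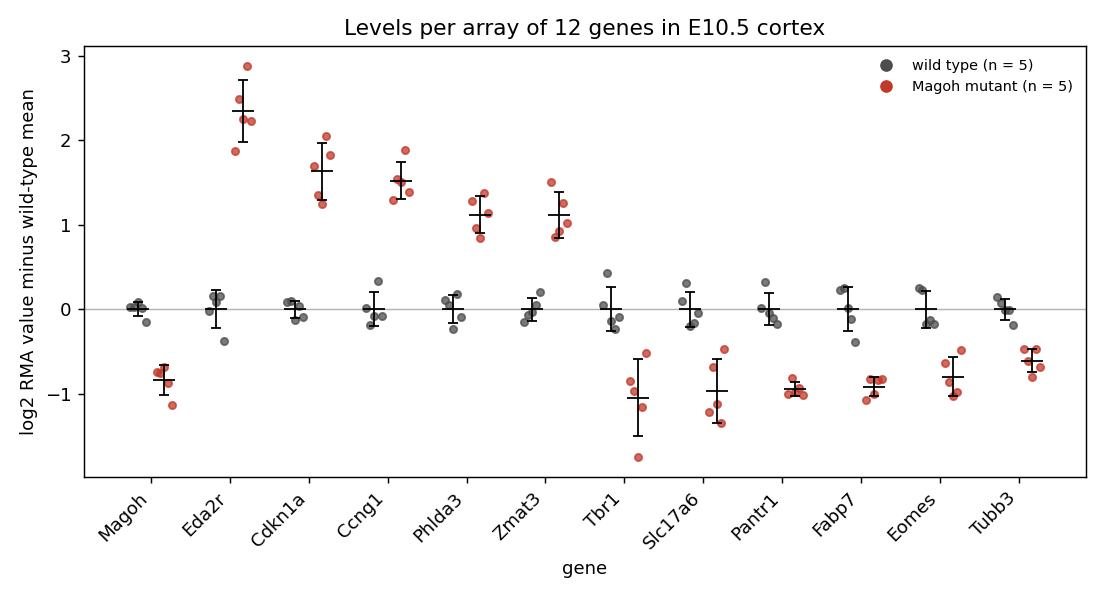
Log2 RMA value of 12 genes on each array minus the wild-type mean of the gene, for 5 wild-type arrays (grey) and 5 Magoh mutant arrays (red), with horizontal bars for group means and error bars for SD. The mutant arrays lie apart from the wild-type arrays for each gene shown, from Eda2r with a mean difference of 2.35 to Tbr1 with -1.05. Except for Magoh and Tubb3, the genes were chosen for values that did not overlap, so their separation follows from the choice.

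The next largest rises were smaller than those of Eda2r, Cdkn1a, Ccng1, Phlda3 and Zmat3. The adenylate kinase gene Ak1 rose 2.13-fold (limma adjusted p = 0.000251). Sesn2, a stress-induced inhibitor of growth signalling also on the p53 list, rose 1.94-fold, the calcium-activated channel family gene Ano3 1.92-fold and the death receptor gene Tnfrsf10b 1.75-fold. The thiamine transporter gene Slc19a2 rose by 0.73, the insulin receptor substrate Irs4 by 0.71 and the DNA damage gene Ddias by 0.70 on the log2 scale. For Ano3 a second probe set gave 1.31 where the one used gave 0.94, and for Zmat3 a second gave 0.41 where the one used gave 1.12. The wild-type level of Ano3, 5.53 ± 0.14, lay within the medians of the negative controls, 5.34 to 5.82, so its fold is no exact ratio. Ak1, Sesn2, Tnfrsf10b and Irs4 lay below 8.57, the mean 95th percentile of the negative controls, in both genotypes and Slc19a2 in wild type, and their differences can also include background. The call of Irs4 (limma adjusted p = 0.0275) was lost without 6 of the 10 arrays, with adjusted p up to 0.0797.

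Genes of early neurons fell. Tbr1, a transcription factor of the first cortical neurons, fell to 0.484 of its wild-type level, from 6.80 ± 0.26 to 5.75 ± 0.46 (limma adjusted p = 0.00872). Its mutant level lay within the medians of the negative controls, 5.34 to 5.82, and both levels lay below their 95th percentile of 8.57, so this ratio includes background and is not exact. Slc17a6, the vesicular glutamate transporter, fell to 0.510, from 7.06 ± 0.21 to 6.09 ± 0.37 (limma adjusted p = 0.00399), with both levels below 8.57 too, so the same limit holds. Tubb3, the tubulin of young neurons, fell from 10.76 ± 0.13 to 10.15 ± 0.14 (limma adjusted p = 0.00146) and Map2, a dendrite protein gene, from 9.13 ± 0.13 to 8.60 ± 0.09 (limma adjusted p = 0.00226). Dcx, a microtubule protein gene of migrating neurons, fell by 0.73 on the log2 scale (limma adjusted p = 0.0438) with both levels below 8.57, a call lost without 8 of the 10 arrays with adjusted p up to 0.157.

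Of 47 measured neuron genes, 0 rose, 12 fell and 35 did not pass, and adjusted over the list alone 22 fell. The median log2 difference was -0.23 (camera adjusted p = 5.1e-21), with adjusted p = 0.042 with an estimated correlation and 0.0107 with fry. The mean over the list was below the lowest wild-type array in 5 of 5 mutant arrays (exact two-sided permutation p = 0.00794). The number called was 6 without wild-type array 1, 2 or 3 and 7 without wild-type array 4 or mutant array 3 or 4, from 47 tested. Without mutant arrays 1 and 5 together it was 17. Red cell markers had a median of 0.25 and endothelial markers of 0.11, with camera adjusted p = 0.264 and 0.265 with an estimated correlation.

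The step before neurons fell too. Among 28 measured genes of neurogenic commitment, 0 rose, 4 fell and 24 did not pass, and adjusted over the list alone 11 fell. Eomes (Tbr2), a transcription factor of intermediate progenitors, fell by 0.80, Insm1 by 0.41, Myt1 by 0.63 and the proneural gene Neurog2 by 0.44 on the log2 scale, with limma adjusted p of 0.00284, 0.00872, 0.0252 and 0.0254. All 4 lay below 8.57, the 95th percentile of the negative controls, in both genotypes, so the size of these falls is approximate. The call of Myt1 was lost without wild-type array 1, 2 or 3, with limma adjusted p up to 0.102, and that of Neurog2 without wild-type array 2, 3 or 5 or mutant array 2 or 3, up to 0.0891. The list median was -0.17 (camera adjusted p = 1.8e-14), with adjusted p = 0.0837 with an estimated correlation and 0.0177 with fry. The count was 2 without wild-type array 2 or 3 and 10 without mutant arrays 1 and 5 together.

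Apical progenitor genes moved less and in both directions. Of 42 measured, 1 rose, 2 fell and 39 did not pass, and adjusted over the list alone 1 rose and 8 fell. At an unadjusted p under 0.05, 4 were higher and 12 lower. Fabp7, a fatty acid binding protein of radial glia, fell to about 0.529 of its wild-type level (limma adjusted p = 0.000458), with a mutant level below the negative controls' 95th percentile of 8.57, and Id4 by 0.41 on the log2 scale (limma adjusted p = 0.0175), a call lost without wild-type array 1 or 2 with adjusted p up to 0.0796. Lin28a, an RNA-binding protein of early embryonic cells, rose 1.51-fold (limma adjusted p = 0.00633). Hes5, a Notch target, differed by -0.28 (limma adjusted p = 0.0757). The list median was -0.06 (camera adjusted p = 0.00111), with adjusted p = 0.32 with an estimated correlation, and it was -0.04 without wild-type array 5 or mutant array 3. The number that fell was 1 without wild-type array 1 or 2, 5 without mutant array 5 and 9 without mutant arrays 1 and 5 together. Chosen after their values were seen, the progenitor genes Pax6 and Sox1 differed by 0.00 and 0.01 (limma adjusted p = 0.997 and 0.975), with signs that turned in other settings.

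Further large falls were in Pantr1, a long noncoding RNA gene (0.517 of the wild-type level, limma adjusted p = 3.5e-05), Rasgrp1 (0.597), Ptprz1, a receptor phosphatase gene of radial glia (0.613), Gpm6b (0.631), the noncoding RNA gene C130071C03Rik (0.631) and Hpgd (0.639). These ratios are not exact, since all 6 genes lay below 8.57, the 95th percentile of the negative controls, in mutants and all but Gpm6b also in wild type.

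Genes of cholesterol synthesis were lower as a group with no member past the threshold. Of 24 measured, 0 rose, 0 fell and 24 did not pass in limma, while 11 were lower at an unadjusted p under 0.05 and 5 fell adjusted over the list alone. In 23 of 24 the difference was negative, with Insig1 at -0.28, Lss at -0.27 and Cyp51 at -0.36. The median was -0.17 (camera adjusted p = 7.9e-11), with adjusted p = 0.0129 with an estimated correlation and 0.000961 with fry, and the list mean was lower in 5 of 5 mutant arrays (exact two-sided permutation p = 0.00794).

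Of 33 measured genes driven by the stress factor Atf4, 3 rose, 0 fell and 30 did not pass, and adjusted over the list alone 4 rose. They were Sesn2 (0.95), which is also on the p53 list, Asns (0.41), the asparagine synthetase gene, and Atf4 itself (0.31, limma adjusted p = 0.0248). The list median was 0.06 (camera adjusted p = 0.000286), with adjusted p = 0.154 with an estimated correlation and 0.0169 with fry. Without mutant array 5 the median was 0.04. The call of Atf4 was lost without 6 of the 10 arrays, with limma adjusted p up to 0.0878. Ribosomal protein genes, of which 0 of 83 rose or fell in limma (9 higher and 0 lower at an unadjusted p under 0.05, and 0 adjusted over the list alone), had a median of 0.06 (camera adjusted p = 5.5e-06), with adjusted p = 0.379 with an estimated correlation.

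**Figure D2:**
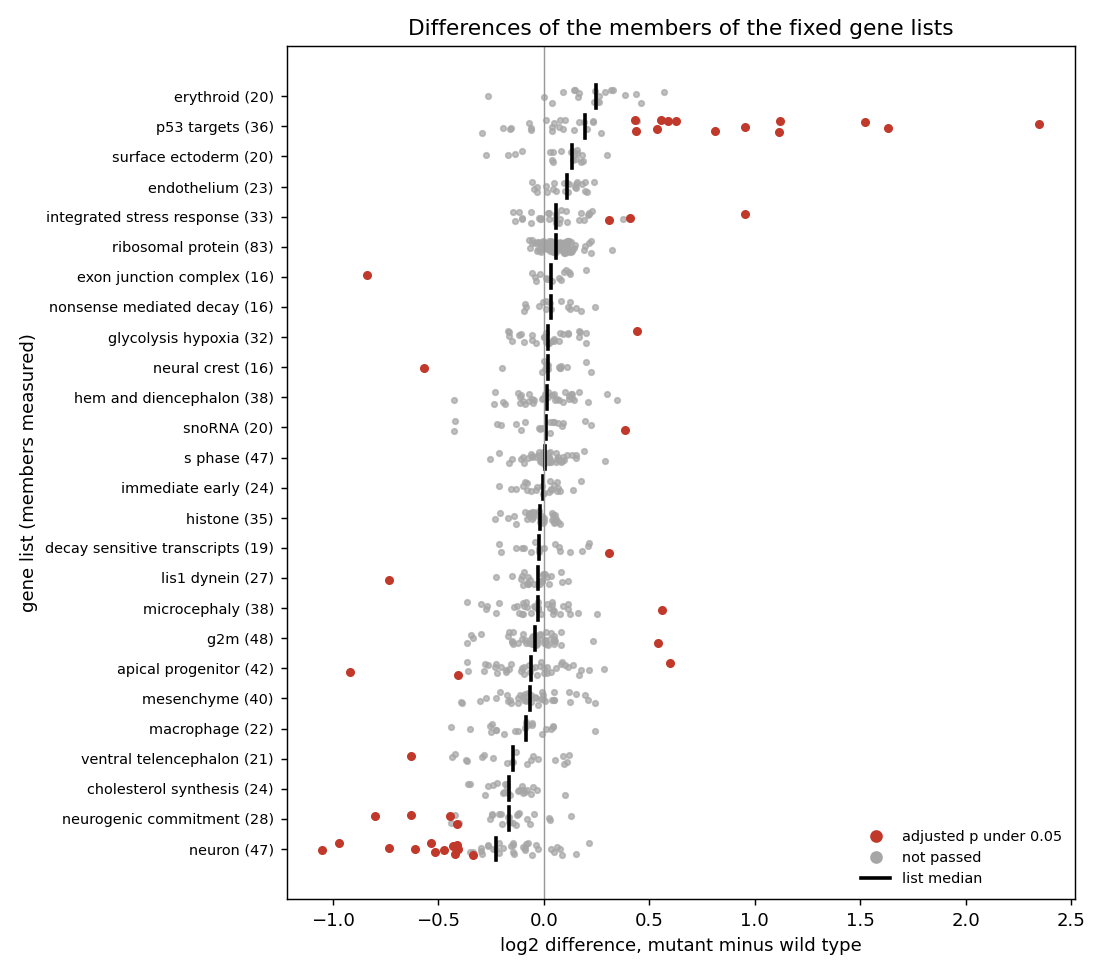
Log2 difference, mutant minus wild type, of each measured member of 26 gene lists (number measured in brackets), with called genes in red, others in grey and the list median as a black bar. The p53 targets extend to 2.35 and the neuron genes to -1.05.

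Markers of other cells in the dissection moved in part with these groups. Of 20 red cell genes, 0 rose or fell in limma (12 higher at an unadjusted p under 0.05) and 9 rose adjusted over the list alone, with Slc4a1 at 0.44, Epor at 0.29 and Gata1 at 0.25, the last 2 at levels below 8.57. Their median was 0.25 (camera adjusted p = 4.3e-09), with adjusted p = 0.264 with an estimated correlation, and the list mean was higher than the wild-type mean in 4 of 5 mutant arrays (exact two-sided permutation p = 0.0873, adjusted over 27 lists 0.236). Of 23 endothelial genes, 0 passed (4 higher at an unadjusted p under 0.05), with a median of 0.11 (camera adjusted p = 0.000487), and adjusted p = 0.265 with an estimated correlation. Their list mean was above the wild-type mean in 5 of 5 mutant arrays, with overlap between the genotypes (exact two-sided permutation p = 0.0317, adjusted over 27 lists 0.107). Surface ectoderm genes (20 measured, 0 called, 2 higher and 1 lower at an unadjusted p under 0.05) had a median of 0.13 (camera adjusted p = 0.0475), with adjusted p = 0.561 with an estimated correlation. The camera call was lost without wild-type array 1, 2, 3 or 5 or mutant array 4 or 5 (adjusted p up to 0.277), and without mutant array 4 the median was 0.08. Macrophage genes were lower (22 measured, 0 called, 8 lower at an unadjusted p under 0.05, median -0.09, camera adjusted p = 2.6e-05), with adjusted p = 0.142 with an estimated correlation. Mesenchyme genes had a median of -0.07 (40 measured, 0 called, 7 lower and 2 higher at an unadjusted p under 0.05, camera adjusted p = 0.0109), with adjusted p = 0.505 with an estimated correlation. The camera call was lost without wild-type array 4 or mutant array 3 (adjusted p up to 0.133), and without mutant array 2 the median was -0.04. Of 21 ventral telencephalon genes, 0 rose, 1 fell and 20 did not pass, and adjusted over the list alone 7 fell. That 1 was the homeobox gene Dlx1 (-0.63, limma adjusted p = 0.0195, with both levels below 8.57), whose call was lost without wild-type array 1 or 2 with adjusted p up to 0.0821, and the median was -0.15 (camera adjusted p = 5.5e-06), with adjusted p = 0.198 with an estimated correlation. The means of the macrophage and the ventral telencephalon list were each below the wild-type mean in 5 of 5 mutant arrays, with overlap between the genotypes (exact two-sided permutation p = 0.0159 for both, adjusted over 27 lists 0.0612). For surface ectoderm and mesenchyme the exact two-sided permutation p was 0.175 and 0.214. Adjusted over the list alone, 6 macrophage and 3 mesenchyme genes fell, 1 surface ectoderm gene rose and 1 fell, and 0 endothelial genes passed.

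**Figure D3:**
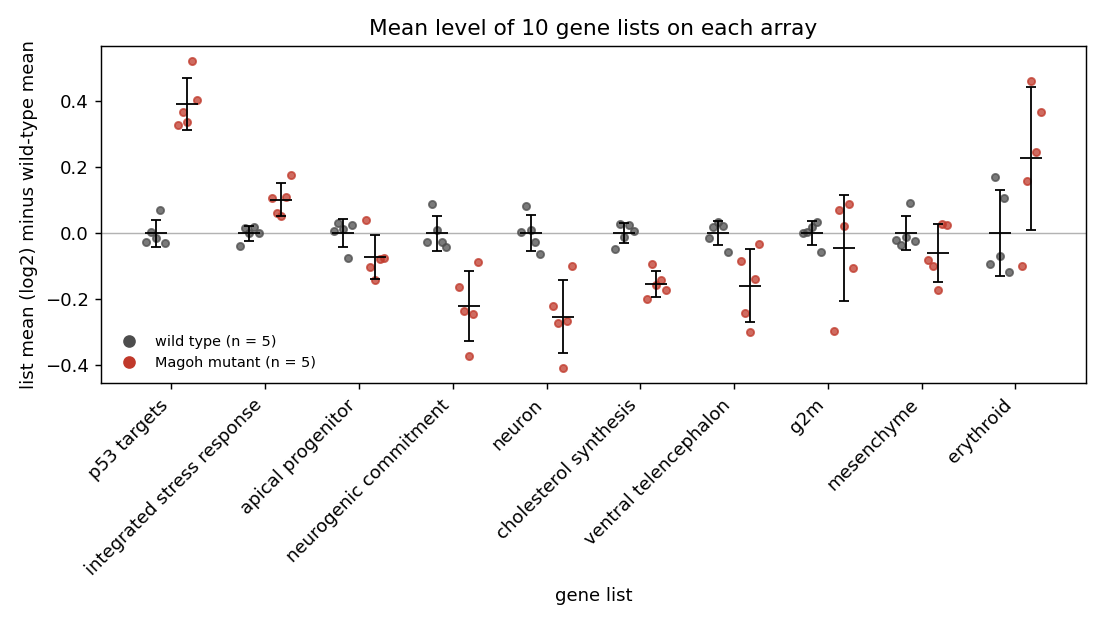
Mean of 10 gene lists on each array minus the wild-type mean of that list, in log2 units, for 5 wild-type arrays (grey) and 5 Magoh mutant arrays (red), with bars for group means and SD. The p53 list mean lay between 0.33 and 0.52 in mutants and the neuron list mean between -0.41 and -0.10.

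Gene groups tied to the known roles of the exon junction complex did not pass by camera. Each gene had 1 value that summarises its probes. Changes in splicing, or in single isoforms that decay would clear, were therefore not tested. Nonsense-mediated decay factors (16 measured, 0 called, 2 higher at an unadjusted p under 0.05) had a median of 0.03 (camera adjusted p = 0.0746). Relative to the wild-type mean, their list mean was 0.04 to 0.15 on mutant arrays 2 to 5, above the highest wild-type array (0.02). On mutant array 1 it was -0.09 (exact two-sided permutation p = 0.27 over all arrays). Of 19 transcripts cleared by that decay, 1 rose (Atf4), 0 fell and 18 did not pass (camera adjusted p = 0.801), with a median of -0.02 against a mean of 0.02. Of 38 genes whose loss gives a small brain, 1 rose (Cdk6, by 0.56), 0 fell and 37 did not pass (camera adjusted p = 0.423). The call of Cdk6 was lost without wild-type array 1 or 2, with limma adjusted p up to 0.0563. The Lis1 and dynein list had 27 measured members, of which 1 fell (Dcx) and 26 did not pass (camera adjusted p = 0.0552). Of 48 genes of G2 and mitosis, 1 rose (Gtse1, by 0.54 from a wild-type level below 8.57) and 47 did not pass (camera adjusted p = 0.125), and of 47 genes of S phase 0 passed (3 higher and 1 lower at an unadjusted p under 0.05, camera adjusted p = 0.449). Adjusted over the list alone, the counts of these lists were the same.

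The remaining lists showed single genes at most. Of 32 glycolysis and low-oxygen genes, 1 rose (the glucose transporter gene Slc2a3, by 0.44, limma adjusted p = 0.0422) and 31 did not pass (camera adjusted p = 0.284). Of 16 neural crest genes, 1 fell (the endothelin receptor gene Ednrb, by 0.57 on the log2 scale) and 15 did not pass (camera adjusted p = 0.525). Of 20 small nucleolar RNA genes, 1 rose (Snora44, by 0.39, limma adjusted p = 0.0461) and 19 did not pass (camera adjusted p = 0.806), with a median of 0.01 against a mean of -0.02. Ednrb and Snora44 lay below 8.57, the 95th percentile of the negative controls, in both genotypes, so these sizes are approximate. Without 7 and 8 of the 10 arrays in turn, the calls of Slc2a3 and Snora44 were lost, with limma adjusted p up to 0.142 and 0.146. Lists with 0 called genes were dorsal midline and diencephalon (38 measured, 1 higher and 2 lower at an unadjusted p under 0.05, camera adjusted p = 0.922), immediate early (24 measured, 1 lower, camera adjusted p = 0.684), histone (35 measured, 1 lower, camera adjusted p = 0.308) and sex-linked genes (5 measured, 0 at an unadjusted p under 0.05, camera adjusted p = 0.922). Adjusted over the list alone, 1 dorsal midline and diencephalon gene fell, and the counts of the other lists in this paragraph were the same. In each genotype 3 of 5 arrays had high levels of Y-linked genes.

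In all, 53 of 20405 genes were higher and 64 lower in mutants (limma, adjusted p under 0.05), and 1888 had an unadjusted p under 0.05 where 1020 would be expected by chance. Over all 20405 genes, the values of the 2 genotypes did not overlap for 575, where chance gives 0.794% of genes. Differences of at least 2-fold were seen for 6 of the higher and 1 of the lower genes. By camera with the preset correlation 13 of 27 lists passed, 6 upward and 7 downward, against 3 with an estimated correlation and 5 with fry. Mutant arrays 1 and 5 stood apart on the first principal component (29.0 and 10.8, against -9.61 to 0.32 for the other 8), which held 30.1% of the variance. Leaving out mutant array 1 raised the counts to 89 and 96, leaving out both arrays raised them to 253 and 249, and leaving out wild-type array 1, 2, 3 or 5 gave 32 to 34 higher genes. Without wild-type array 1, 2 or 3 there were 34, 31 and 37 lower genes.

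The genes near Magoh were compared with the rest of the genome, since sequence linked to a mutation can differ between strains. Within 20 Mb of Magoh 9 of 373 genes (2.41%) had an unadjusted p under 0.01, against 682 of 20031 elsewhere (3.41%), an odds ratio of 0.701 (95% interval 0.317 to 1.35, Fisher's exact test, two-sided p = 0.384). Without wild-type array 4 the ratio was 1.01. Zfp991 and Zfp992, neighbouring zinc finger genes of distal chromosome 4 singled out after their values were seen, rose by 0.45 and 0.48 (limma adjusted p = 0.012 and 0.00564). The call of Zfp991 was lost without wild-type array 1 or 2, with limma adjusted p up to 0.0563. They belong to a family of near-identical copies whose probes can cross-hybridise.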

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

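The counts over other splits of the arrays for genes higher and genes lower, and the test of mutant arrays 1 and 5 left out together, were chosen only after the results were seen.

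In 9 of 172 groups of 5 values tested, 1 array lay far from the other 4, by a gap to its neighbour above 0.71 of the whole range, where chance alone gives 8.6. Among mutants, Ano3 was highest on array 4 (7.01, the others 6.24 to 6.43, gap 0.754 of the range), Ptprz1 was lowest on array 5 (7.40, the others 7.74 to 7.81, gap 0.832), Pax6 was lowest on array 5 (9.05, the others 9.40 to 9.51, gap 0.758) and the endothelial gene Cdh5 was highest on array 1 (8.87, the others 8.48 to 8.59, gap 0.717). Among wild types, Rasgrp1 was highest on array 2 (7.61, the others 7.26 to 7.34, gap 0.759), as was Gad2 (7.56, the others 7.17 to 7.26, gap 0.778). Wild-type array 4 had the lowest mean of the apical progenitor list (-0.07, the others 0.01 to 0.03, gap 0.774) and the highest means of the mesenchyme list (0.09, the others -0.04 to -0.01, gap 0.807) and the surface ectoderm list (0.16, the others -0.08 to -0.02, gap 0.75).

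The rise of p53 targets was set against handling stress, a single array and the grouping of arrays. Handling stress would raise immediate early and heat shock genes, whose median log2 difference was -0.00114 and whose list mean differed by at most 0.0456 (upper 95% bound, exact one-sided permutation p = 0.659). A single mutant array did not carry the rise, since at least 11 targets were called with each mutant array left out, against 13 with all arrays. Over 100 splits of the 10 arrays, 1, the real one, gave a mean difference as large as 0.391 (highest other 0.288). The list means of the 2 genotypes did not overlap, so the real split had to give the largest difference. That count therefore adds nothing to the exact permutation test of the same means. A response to the mutation may be a candidate explanation, while litter and hybridisation day stay open because they could not be tied to the arrays.

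The fall of neuron genes was set against other tissue in the dissection, younger embryos and the 2 mutant arrays that stood apart. Dilution by tissue that holds neither set of transcripts would lower progenitor and neuron genes alike. The apical progenitor list lay above the neuron list by 0.182 (95% interval 0.062 to 0.287, exact two-sided permutation p = 0.0159). This argues against such dilution as the whole cause. Tissue that itself holds progenitor transcripts could give the same difference, so the test cannot count against it. The part of the prediction that no list of other tissue be called was not met, because red cell, endothelial and surface ectoderm lists passed at the preset correlation, so a smaller admixture stays open too. Whether mutant embryos were younger cannot be told apart from genotype here, since the early globin Hbb-bh1 relative to Hbb-y differed by 0.072 (95% interval -0.203 to 0.332, exact two-sided permutation p = 0.508). Mutant arrays 1 and 5 had the smallest falls of the neuron list mean, -0.22 and -0.10, against -0.27, -0.41 and -0.27 on mutant arrays 2, 3 and 4. Those arrays therefore did not carry the fall, and leaving them out could only deepen its mean. Without them the neuron list had a median of -0.28 and a camera adjusted p of 9.69e-19 at the preset correlation. A delay in neuron production may be a candidate explanation alongside age, but it was not tested and other causes were not weighed.

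Zfp991 and Zfp992 on distal chromosome 4 rose together, and sequence of another strain linked to the Magoh allele could account for such a pair. Within 40 Mb of Magoh the odds ratio of genes with an unadjusted p under 0.01 was 0.951 (95% interval 0.594 to 1.45, Fisher's exact test, two-sided p = 0.916), which neither shows nor excludes it. Zfp992 and Zfp991 lay 38.57 and 39.25 Mb from Magoh, near the edge of that window. Among zinc finger genes close to them, Zfp987 and Zfp985 differed by 0.33 and 0.32 without passing (limma adjusted p = 0.0566 and 0.343). Zfp600, Zfp933, Zfp979, Zfp980 and Zfp982 lay between -0.07 and 0.15. Cross-hybridisation among copies of this family was not tested and stays open.

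Over 100 of the 126 splits of the arrays, 1, the real one, called as many as 53 higher genes (highest other 1). Likewise 1 called as many as 64 lower genes (highest other 1). Both counts were thus larger than in any other split drawn. The other splits mix the genotypes, which adds the difference between them to the spread and lowers the calls. A litter or hybridisation day tied to genotype would give the same result. For the 13 gene lists past the threshold at the preset correlation, 27 splits gave as many (highest other 18), so chance cannot be excluded for that count. With an estimated correlation, 1 split, the real one, gave as many as 3 lists (highest other 1). For the genes near Magoh, 72 splits gave as high an odds ratio as 0.701 (highest other 3.71), so chance cannot be excluded.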

How the results depend on the processing

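The fit without mutant arrays 1 and 5 was chosen only after the results were seen. The planned use of the second deposited table was not run, because its columns could not be tied to samples. Among the called genes 0 changed sign in any setting that kept 1 probe set per gene. Magoh lay between -0.88 and -0.76 with any 1 array left out. The number of higher and lower genes was 175 and 233 with array weights, 253 and 249 without mutant arrays 1 and 5 (115 of the 117 called genes were shared), 104 and 120 at an adjusted p under 0.1, and 20 and 17 with a difference of at least 1.5-fold. With 1 array left out it was 32 to 89 higher (lowest without wild-type array 1) and 31 to 96 lower (lowest without wild-type array 2), highest without mutant array 1 in both. Fewer arrays or a changed threshold account for part of this by construction, and otherwise the cause was not tested. The 13 lists became 3 with an estimated correlation and 5 with fry, tests that take more shared variation into account or ask another question, and 12 to 17 with 1 array left out. The odds ratio near Magoh was 0.532 to 1.008, passing 1 without wild-type array 4, and the cause was not tested. Differences near 0 turned sign. For Pax6 they were -0.0022 with quantile normalization, -0.00084 with array weights and -0.062 to 0.079 with 1 array left out, and for Sox1 -0.044 with array weights, -0.047 without mutant arrays 1 and 5 and -0.034 to 0.059. For Magohb they were -0.025 to 0.092 and for Eif4a3 -0.0065 to 0.078 with 1 array left out, and the cause was not tested. Of the values for named genes, 1552 kept direction and side of the threshold, 128 lost the call, 27 gained it and 18 turned sign. For lists, 256 kept both and 30 lost the call. Replicate numbers paired the arrays at most in part. Correlations of same-numbered arrays were 0.011, -0.073, 0.165, 0.36 and 0.062, and for replicate 4 alone was the same number the best partner. Whether the replicate 4 arrays shared a batch was not tested. With the replicate block, Magoh was at -0.84 and 40 genes were higher and 43 lower. Of the neuron list 6 then fell, against 12 without the block, and of the p53 list 13 rose in both. Levels near the negative controls limit dim genes such as Eda2r in wild type.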

Other observations

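The test of let-7 target genes was chosen only after the results were seen, and the values of 4 of its genes had been seen before the list was written.

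A few called genes outside the lists were named after their values were seen. Trim71, a partner of the let-7 pathway in early progenitors, rose by 0.61 (limma adjusted p = 0.00194), the nuclear receptor gene Nr6a1 by 0.58 (limma adjusted p = 0.000231) and the neural tube gene Prtg by 0.69 (limma adjusted p = 0.007). The wild-type level of Trim71 and both levels of Nr6a1 lay below the negative controls' 95th percentile of 8.57, so the size of these rises is approximate. Glycolysis and low-oxygen genes were highest on the replicate 4 array of both genotypes, with list means of 0.17 in wild type and 0.27 in mutant relative to the wild-type mean. On mutant array 1 the list of G2 and mitosis genes was at -0.30, the lowest of the 10 arrays.

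Lin28a and Trim71 act against let-7, so a hypothesis is that let-7 target genes rose as a group. Over 30 measured targets other than Lin28a and Trim71, the mean log2 difference was 0.0597 (95% interval 0.0047 to 0.11, exact two-sided permutation p = 0.0159), with 18 of 30 higher. Over the 26 targets whose values had not been seen, it was 0.0568 (95% interval -0.0032 to 0.117, exact two-sided permutation p = 0.0635), which does not pass. A small rise may be present, but it rests in part on genes already seen and was not adjusted for the other tests.

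Loss of an exon junction protein could act most on long genes, a hypothesis tested across genes. Over 10179 genes in the upper part of expression and outside the neuron list, Spearman rho between genomic span and log2 difference was 0.0156, where a fall of long genes needs a negative value. Because 90 of 100 splits, the real one included, gave a rho at least as large in size (highest other 0.245), the hypothesis was neither borne out nor excluded. Genes are not independent replicates.

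Probe sets left without a match in the gene table, of which 1919 carried an identifier, were tested apart. Of 5224, 0 were higher and 0 lower in limma at an adjusted p under 0.05, while 328 had an unadjusted p under 0.05.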
